A study of Mus musculus with 10 samples.

How the data were processed

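Mouse placenta was profiled with the Chromium Single Cell 3′ version 3 kit and sequenced on an Illumina NovaSeq. The labels list 10 samples, 5 of each genotype, Adar1 ko and Adar1 wt. The title and design speak of nuclei, while the protocol describes a cell suspension made with collagenase A, red cell lysis and removal of dead cells; "cell" is used here for a barcode. The authors deposited 1 matrix of UMI counts per genotype, unnormalised, with barcodes already filtered, and 1 summary of run metrics per genotype in numbers and in percent, as the deposited file headers give them. The counts were made with Cell Ranger 4.0.0 and genome build mm39, per the submitters' processing notes; the annotation release is not stated. Each matrix pools the 5 samples of its genotype, all barcodes carry 1 suffix, and nothing ties a cell to a sample or says whether the 5 were separate animals. The sample numbering and the file names in the descriptions would fit sequencing lanes as well. Each matrix was therefore taken as 1 sample, and neither a test across samples nor a paired or leave-one-out analysis could be made.

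The matrices hold 32285 features with 32245 symbols. Identifiers sharing a symbol were summed, which concerns 38 symbols, Ddit3 among them. Positions are those of the GENCODE vM21 annotation, which is on GRCm38 and not on the build the submitters name. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Figures were drawn with matplotlib 3.10.9, and the TMM factors came from edgeR 4.0.16 in R 4.3.3.

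Barcodes with fewer than 500 genes (164 labelled knockout and 220 labelled wild type) or with over 20% mitochondrial UMIs (7 and 2) were left out. Scrublet, as implemented in scanpy and with its automatic threshold, marked 532 of 12434 and 636 of 12354 cells as doublets (4.28% and 5.15%), which were removed. The retained cells held 72360837 and 98333740 UMIs.

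Both matrices were clustered together, without batch correction since batch and genotype are the same. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen after leaving out 475 genes of the response lists, so that the responses under study would not drive the clusters, along with hemoglobin, mitochondrial, ribosomal protein, Xist and Y-linked genes. From 30 principal components and 15 neighbours, Leiden clustering at resolution 1 gave 29 clusters (seed 1). A cluster took the name of the class with the most markers when at least 3 of them were at least 2-fold higher than in the other cells and were found in at least 10% of its cells; 22 marker classes, 8 of them trophoblast, were written before the data were examined. A cluster whose 10 leading genes held at least 2 more markers of another class than of its own was left unnamed, and so was the cluster led by Trpv6 and S100g. These 2 naming rules were set after the clusters had been seen. Trophoblast clusters with tied or conflicting subtype markers, 5 and 12, were left as trophoblast of unresolved type and clusters 8, 11 and 21 were unnamed; they are given by number. Names end in "-like" because they rest on RNA alone. Trophoblast is the sum of all trophoblast classes with clusters 5 and 12.

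UMIs were summed over all retained cells, over trophoblast, and over each class with at least 50 cells in both libraries, and divided by the total of the same cells to give counts per 1000000 (CPM). Sums carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all for counting error only. A sum under 3 UMIs or cells was set to a floor of 3 in ratios, which makes a fold against 0 a lower bound, and a share of 0 cells is given with 3 cells of the total as its limit; no fold was given where both sums were at or under 3. These intervals do not hold the variation between animals, litters or preparations, which cannot be estimated here.

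The 21 gene lists were written before the data were examined; 3 examples of their coverage are 76 of 79 interferon-stimulated genes, 26 of 28 interferon gamma genes and 59 of 60 integrated stress response genes found by symbol. Mx1, Mx2, Oas1b, Gbp11, Cxcl11 and Mars1 were absent from the features. Some genes, such as Eif2ak2 and Sesn2, stand on several lists, so the lists are not independent. A member counted as measured with at least 20 UMIs over both libraries. Each list was described by the median log2 ratio of its members with an order-statistic interval, by the members over 2-fold higher or lower, and by its rank among 10000 random lists matched on 20 expression bins, which is a description and not a p-value. The set of 90 ribosomal protein genes was added by class after the data had been seen.

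Genes are named by a rule also set before the data were examined: 28 fixed genes; the 10 largest and 10 smallest ratios in all cells and in trophoblast among genes with at least 100 UMIs and 20 CPM in either library, leaving out hemoglobin, mitochondrial, ribosomal protein, Xist, Y-linked, Gm and Rik genes; the 3 largest and 3 smallest per class at 50 CPM; and up to 4 examples per list, the most abundant past 2-fold, or 2 where none was. Genes leading a cluster of 1 library are pointed out where they are named. For the share of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out. The thinning was changed to a single draw shared by all uses after thinned values had been seen.

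The methods were tested on simulated data, made by drawing Poisson counts for both libraries from the same gene rates at their own depths, with a known fold given to 200 genes, and so without variation between samples. Intervals covered the truth for 95.6%, 95.7% and 96.2% of genes without a difference in all cells, trophoblast and decidual stroma-like cells. For folds of 1.5, 2 and 4 they covered it for 95.5%, 97.0% and 97.0% of genes in trophoblast and for 94.0%, 89.6% and 92.4% in decidual cells, and they excluded 1 for 86.6%, 100% and 100% in trophoblast and 68.7%, 97.0% and 100% in decidual cells. Of 200 lists without a difference, 6%, 4.5% and 7.5% fell outside the central 95% of random lists. Thinning reduced a difference between depths from 22.2 to −0.0676 percentage points.

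Alternatives were median-ratio and TMM scaling; totals without hemoglobin, mitochondrial and ribosomal protein genes; the mean of per-cell values; thinned sums; list minimums of 1 and 100 UMIs; 1.5-fold counts; all deposited barcodes, at least 1000 genes or at most 10% mitochondrial UMIs; doublets kept; resolutions of 0.5 and 2; variable genes with the response lists; each matrix clustered alone; thinning to 2000 UMIs or none; and shares without erythroid-like cells. Added after the data were seen were trophoblast without clusters over 90% of 1 library, with cluster 11, or with its classes weighted alike; totals without the 20 most abundant genes; and shares without decidual cells or of trophoblast only.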

Results

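RNA of single nuclei or cells was profiled from mouse placenta carrying 2 labelled genotypes, Adar1 knockout and Adar1 wild type. Adar encodes ADAR1, which converts adenosine to inosine in double-stranded RNA and so keeps the cell's own RNA from being sensed as foreign. The series names its groups as floxed Adar1 and Adar1PKO placentas, and its title places the question in innate immunity, endogenous double-stranded RNA and the integrated stress response. There were 10 listed samples, 5 per genotype, but the counts were deposited as 1 matrix per genotype with no record linking a cell to a sample, and nothing in the labels says that the 5 were separate animals. Each genotype is therefore 1 sample here: no difference has a replicate check and no test was run. All intervals are at 95%. Those of levels, ratios and shares cover counting error only, and those of list medians are order-statistic intervals over the member genes. The gestational age is not in the labels.

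The library labelled knockout held 12600 barcodes with 78856831 UMIs, and the library labelled wild type 12575 barcodes with 108589686 UMIs. After filtering, 11902 and 11718 cells remained, with medians of 4635 and 6722.5 UMIs and of 2242 and 2857 genes per cell. Exonic reads made up 32.1% in the library labelled knockout and 27.2% in the other, and intronic reads 55.6% and 60.7%, per the submitters' metrics. Mitochondrial UMIs were 0.280% and 0.157% of the total, ribosomal protein UMIs 0.749% and 0.441%, and hemoglobin UMIs 0.0401% and 0.0892%.

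Adar RNA was higher, not lower, in the library labelled knockout. Over all cells Adar (ENSMUSG00000027951; chromosome 3, 89715022 to 89753446 on GRCm38) stood at 147 CPM (UMIs per 1000000; 10653 UMIs) against 64.0 CPM (6294 UMIs) in the library labelled wild type, a ratio of 2.30 (2.23 to 2.37). In trophoblast, the fetal epithelium of the placenta, it was 169 against 64.9 CPM, a ratio of 2.61 (2.52 to 2.71). Ratios within cell classes ranged from 1.28 (0.903 to 1.81) in cluster 11 to 6.67 (5.16 to 8.78) in cluster 5, and the decidual stroma-like cells stood at 2.23 (1.88 to 2.66). The method counts RNA near the 3′ end together with unspliced RNA, and the deleted part of the gene is not given, so the level of Adar checks neither the deletion nor the labels. The libraries are therefore named below by their labels. Without the 4 trophoblast clusters of which over 90% of cells came from 1 library, the trophoblast log2 ratio of Adar was 2.07 in place of 1.38.

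The 2 libraries differed in their cell classes, trophoblast subtypes and decidual cells among them. Trophoblast cells made up 44.6% (43.7 to 45.5; exact Clopper-Pearson interval) of the library labelled knockout and 66.9% (66.0 to 67.7) of the library labelled wild type. Cells resembling sinusoidal trophoblast giant cells, which line the maternal blood spaces, made up 0.361% (0.262 to 0.486) against 9.79% (9.26 to 10.3) at the main clustering, 27.1-fold lower. The size of this difference depended on the clustering, as the log2 ratio of the share was −0.95 at a Leiden resolution of 0.5. Cells resembling decidual stroma, the maternal tissue beside the placenta, made up 19.8% (19.1 to 20.5) against 3.36% (3.04 to 3.70), 5.89-fold higher. Glycogen cell-like trophoblast was lower, at 7.46% against 24.1%, as was spongiotrophoblast-like, at 5.91% against 12.1%. Endothelium-like cells were higher, at 14.7% against 7.62%. Syncytiotrophoblast I-like cells, which face the maternal blood, held a similar share of all cells, 11.1% against 11.8%, and syncytiotrophoblast II-like cells 4.00% against 5.58%. Of trophoblast alone, syncytiotrophoblast I-like cells made up more, 24.9% (23.7 to 26.1) against 17.6% (16.7 to 18.4). Syncytiotrophoblast II-like cells made up 8.97% (8.22 to 9.77) against 8.35% (7.74 to 8.98). Glycogen cell-like (16.7% against 36.0%) and spongiotrophoblast-like cells (13.2% against 18.2%) stayed lower.

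Smaller classes were pericyte or mesenchyme-like cells (5.16% and 5.57% in the libraries labelled knockout and wild type), macrophage or monocyte-like cells (2.26% and 1.65%), natural killer-like cells (0.899% and 0.307%) and erythroid-like cells (0.597% and 1.21%). B cell-like cells held 0.664% and 0.632%, T cell-like cells 0.353% and 0.555%, and yolk sac-like cells 0.218% and 0.358%. The trophoblast clusters 5 and 12, whose subtype was not resolved, held 10.1% and 5.60% of the library labelled knockout and 1.68% and 1.83% of the other. Of the 3 unnamed clusters, cluster 8 held 4.43% and 5.46%, cluster 11, led by Trpv6 and S100g, 3.27% and 6.14%, and cluster 21 3.08% and 0.265%, 11.7-fold higher in the library labelled knockout.

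Several classes consisted of different clusters, or of clusters in different proportions, in the 2 libraries, and a cluster mostly of 1 library may be that library's own. The syncytiotrophoblast I-like cells were nearly all of cluster 9 in the library labelled knockout (1313 of 1321 cells) and of cluster 27 in the other (1342 of 1377). The spongiotrophoblast-like cells were of clusters 6 and 22, with 692 and 11 cells labelled knockout and 352 and 1071 labelled wild type. Cluster 6 was led in part by the immune genes Acod1, Oasl1 and Pla2g7. The glycogen cell-like cells were split between clusters 4 and 10 in ratios of 505 to 383 and 890 to 1934. Clusters 2 and 13, both decidual stroma-like, held 695 and 274 cells labelled knockout and 38 and 2 labelled wild type. The number of sinusoidal giant cell-like cells depended on the clustering, as 712 and 1357 cells carried the name at a Leiden resolution of 0.5. Cluster 12, left unresolved, met most markers of that class, 4 of 9, followed by 3 of parietal giant cells. It held 667 cells labelled knockout and 214 labelled wild type.

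**Figure D1:**
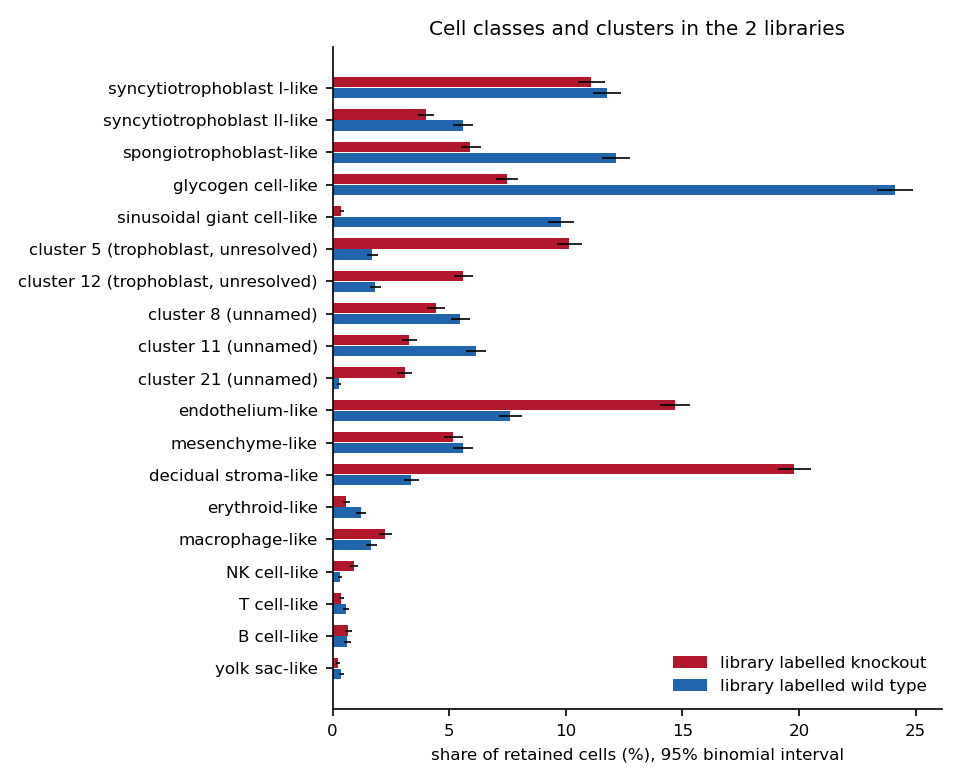
Share of retained cells (%) in each cell class and numbered cluster, in the library labelled knockout and the library labelled wild type; bars start at 0 and error bars are exact 95% binomial intervals for counting error. Decidual stroma-like cells stand at 19.8% against 3.36%, and sinusoidal giant cell-like cells, whose number depended on the clustering, at 0.361% against 9.79%.

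Genes induced by interferon were higher in trophoblast of the library labelled knockout. This main comparison asked which genes differ between the genotypes within the fetal compartment (5306 and 7836 cells, 41201022 and 79850592 UMIs). Its sums still mix trophoblast subtypes, whose shares differed between the libraries. Of 74 measured type I and III interferon-stimulated genes, 63 were over 2-fold higher in the library labelled knockout and 1 was over 2-fold lower. Their median log2 ratio was 2.55 (2.16 to 3.18), above each of 10000 random lists matched on expression. Rsad2, which encodes the antiviral enzyme viperin, was 433 against 28.0 CPM, 15.5-fold higher (14.8 to 16.2). Oasl2, of the oligoadenylate synthetase family, was 5.44-fold higher, Trim25, a ubiquitin ligase of RNA sensing, 2.65-fold higher, and Ddx58, the RNA sensor RIG-I, 3.38-fold higher. Isg15, a ubiquitin-like modifier, was 94.2 against 11.4 CPM, 8.28-fold higher (7.70 to 8.91), Ifit1, which binds foreign RNA, 12.3-fold (11.1 to 13.6), the transcription factor Irf7 5.43-fold and the interferon signal transducer Stat1 3.19-fold.

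Over all 19781 genes with at least 20 UMIs in trophoblast, the median log2 ratio was 0.17 under CPM, 0.04 under median-ratio scaling and −0.03 under TMM scaling. Relative to this shift of 0.17, the interferon-stimulated genes stood at 2.37. Without the 4 clusters mostly of 1 library their median was 3.19 before that subtraction. Among 15583 trophoblast genes with at least 100 UMIs, 1846 were over 2-fold higher and 978 over 2-fold lower under CPM, against 1351 and 1349 under TMM scaling, so the balance of the whole transcriptome depended on the scaling.

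All 22 measured genes of the interferon gamma response and GTPase list were over 2-fold higher in trophoblast of the library labelled knockout, with a median log2 ratio of 3.39 (2.46 to 4.19; 3.22 relative to all genes). Among them, Cd274, which encodes the immune checkpoint ligand PD-L1, was 117 against 11 CPM, and the guanylate-binding proteins Gbp3 and Gbp7 were 22.8-fold and 6.88-fold higher. Irgm2, another interferon-inducible GTPase, was 4.20-fold higher, and the chemokine gene Cxcl10 stood at 21.9 against 0.200 CPM, a ratio of 109 (66.9 to 192). Of 19 measured genes of MHC class I antigen presentation, 13 were over 2-fold higher and none lower (median 1.42, 0.80 to 1.84; 1.25 relative to all genes). The class I heavy chains H2-K1 (511 against 162 CPM) and H2-D1 (235 against 71.0 CPM), their partner B2m (2.16-fold) and Tapbp, a chaperone of peptide loading (2.78-fold), were higher.

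UMIs of the interferon genes Ifnb1, Ifnl2 and Ifnl3 were found in the library labelled knockout and not in the other, while Ifnk, a gene chosen after its values were seen, had 17 and 21 trophoblast UMIs. Ifnb1, encoding interferon beta, had 147 UMIs in its trophoblast cells and 0 in the other library, at least 95-fold higher against a floor of 3 UMIs. The interferon lambda genes Ifnl3 and Ifnl2 had 64 and 19 UMIs against 0, at least 41.3-fold and 12.3-fold higher. Of 11902 cells labelled knockout 60 held such UMIs, 30 of them spongiotrophoblast-like and 23 in cluster 5, while 0 of 11718 cells labelled wild type did. At the floor of 3 cells this allows a share of cells with such a UMI of up to 0.0256%, and it sets no limit on cells expressing the genes. The list of interferons and their receptors as a whole had a median of 0.54 (−0.16 to 5.37; 0.36 relative to all genes), with 2 of 9 measured members over 2-fold higher.

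Genes for sensing and editing double-stranded RNA divided. Of 29 measured, 11 were over 2-fold higher and none lower (median 0.44, 0.18 to 1.38; 0.27 relative to all genes). Ifih1, the sensor MDA5, was 304 against 88.9 CPM, 3.42-fold higher (3.32 to 3.52), Eif2ak2, the kinase PKR that phosphorylates eIF2α, 3.61-fold (3.47 to 3.74), and Zbp1, a sensor of Z-form nucleic acid, 17.6 against 1.21 CPM, 14.5-fold (11.7 to 18.1). Mavs, the adaptor downstream of MDA5 and RIG-I, was 1.24-fold lower (1.15 to 1.34), and Adarb1, which encodes the related editing enzyme ADAR2, was 1.85-fold lower (1.74 to 1.96). Adarb2, a brain-enriched member of the family, was near the detection limit at 1.70 against 0.939 CPM. Ifih1, Ddx58, Dhx58, Eif2ak2, Zbp1 and Trim25 also stand on the interferon-stimulated list, so the results of these lists are not independent.

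**Figure D2:**
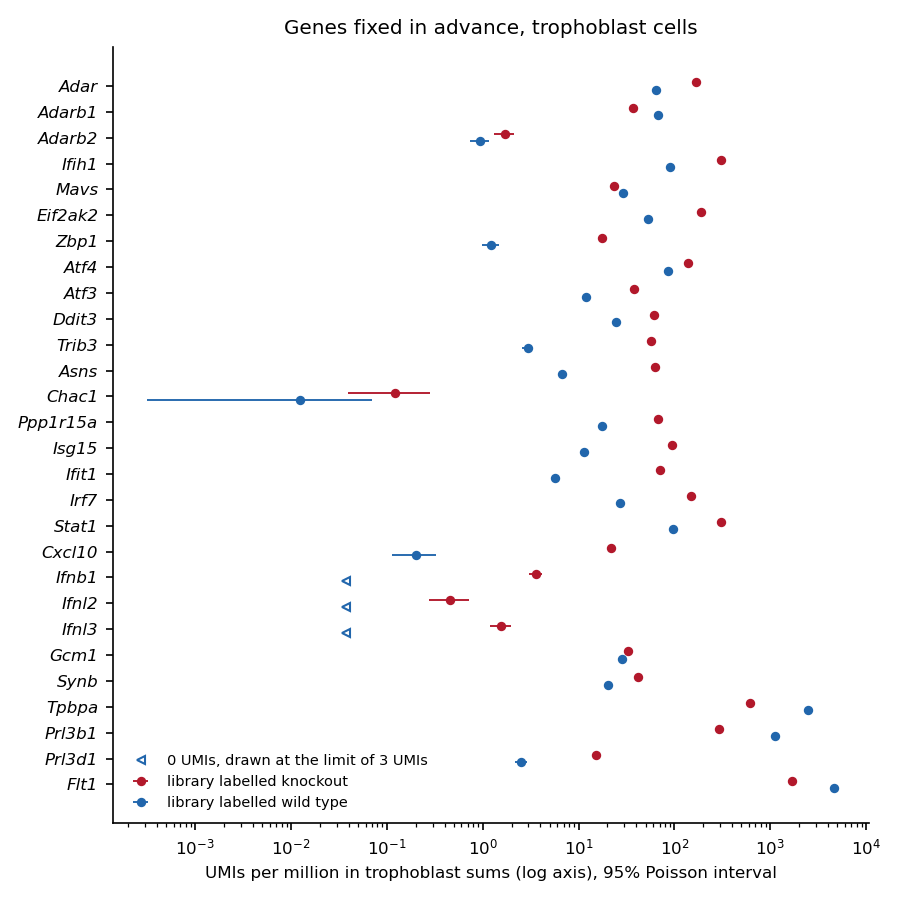
Level of the genes fixed in advance in trophoblast, in CPM on a log axis, with points for the library labelled knockout and the library labelled wild type, 95% Poisson intervals, and open triangles at the limit of 3 UMIs where no UMI was seen. Isg15 stands at 94.2 against 11.4 CPM, Trib3 at 57.0 against 2.94 CPM and Mavs at 23.3 against 29.0 CPM.

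The share of trophoblast cells with a UMI was higher in the library labelled knockout for every gene chosen for this count but Chac1, with every cell thinned to 1000 UMIs, which left 69 and 76 shallower cells out of 5306 and 7836. Isg15 was seen in 9.80% (9.0 to 10.6) against 1.22% (0.992 to 1.49) of cells, Stat1 in 24.8% against 8.27%, Adar in 16.2% against 6.22%, Ifit1 in 6.11% against 0.503% and Zbp1 in 2.04% against 0.0773%. For Asns the shares were 6.70% against 0.838%, and for Trib3 5.94% against 0.322%. Chac1 was seen in 1 cell of the library labelled knockout (0.0191%) and in 0 of 7760 in the other (0.0387% at the floor of 3 cells), too few to compare. Unthinned, Isg15 was seen in 37.0% and 9.12%, with median depths of 6377.5 and 8610.5 UMIs. In erythroid-like cells (54 and 94 cells, 17 and 48 left out; median depths 2065 and 1277.5 UMIs) the thinned shares were 1.85% (0.0469 to 9.89) and 3.19% (0.663 to 9.04) for both Isg15 and Trib3, and Ifit1 was seen in 3 of 54 cells (5.56%) and in 0 of 94. No class surely lacks these genes and these cells were few, so the background was not measured.

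The integrated stress response, in which phosphorylated eIF2α favours translation of ATF4 and ATF4 induces its target genes, was higher as a group. Of 57 measured targets of ATF4 and CHOP in trophoblast, 34 were over 2-fold higher and none lower in the library labelled knockout, with a median of 1.18 (0.88 to 1.44; 1.01 relative to all genes). Trib3, a pseudokinase induced by CHOP, was 57.0 against 2.94 CPM, 19.4-fold higher (16.9 to 22.2), and Asns, asparagine synthetase, 63.3 against 6.76 CPM, 9.35-fold (8.52 to 10.3). The tRNA synthetase genes Yars, Iars and Nars were 2.11-fold, 2.53-fold and 2.70-fold higher, and the transcription factor Cebpb 2.45-fold. Atf4 was 1.60-fold higher (1.54 to 1.66), Atf3 3.17-fold, Ddit3, which encodes CHOP, 2.51-fold, and Ppp1r15a, which encodes the eIF2α phosphatase subunit GADD34, 3.88-fold. Chac1, a glutathione-degrading enzyme, had 5 and 1 UMIs, too few to compare.

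Other measures moved in the same direction as the stress list. Ribosomal protein genes, a set chosen after the data were seen, had a median of 1.11 (1.03 to 1.16) in trophoblast, and the immediate early and heat shock list, which marks stress during tissue handling, a median of 1.30 (0.99 to 2.37; 1.13 relative to all genes) with 18 of 26 over 2-fold higher. Its examples Klf6, Hsp90aa1, Hsph1 and Jund were 2.22-fold, 2.16-fold, 2.30-fold and 3.25-fold higher.

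The eIF2α kinase and phosphatase list had a median of 0.51 (−0.36 to 1.38; 0.34 relative to all genes), and its 3 members over 2-fold higher of 13 were Eif2ak2, Ppp1r15a and Ppp1r15b, the last at 2.59-fold. The ER unfolded protein response, a branch that shares CHOP but acts on protein folding, was lower, with a median of −0.44 (−0.69 to −0.04; −0.61 relative to all genes). Derl3, of the ER degradation machinery, stood at 21 against 81.7 CPM and Sdf2l1 at 3.03 against 10.3 CPM. This direction rested on the clusters mostly of 1 library, without which the list's median was 0.090.

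Inflammatory and death genes were also higher in trophoblast of the library labelled knockout, but the medians of the cell death, p53 and proliferation lists lay below those of the ribosomal protein (1.11) and immediate early genes (1.30), and the NF-kB interval held both. Of 22 measured NF-kB targets and cytokines, 14 were over 2-fold higher and none lower (median 1.61, 0.67 to 2.51; 1.44 relative to all genes); the NF-kB subunits Nfkb1 and Relb were 2.97-fold and 7.30-fold higher, Birc3, a cell death inhibitor, 2.27-fold, and the macrophage growth factor Csf1 2.81-fold. The cell death list had a median of 0.85 (0.40 to 1.60; 0.67 relative to all genes) with 12 of 27 over 2-fold higher. The inflammatory caspase Casp4 was 18.8 against 1.80 CPM, 10.4-fold higher, while Bax and Bcl2l11, which promote apoptosis, were 2.19-fold and 2.75-fold higher and the executioner caspase Casp7 2.25-fold. Of 22 p53 targets, 10 were over 2-fold higher (median 0.92, 0.52 to 1.85; 0.75 relative to all genes), among them the exonuclease gene Aen at 4.59-fold, the stress gene Sesn2 at 2.95-fold and the cell cycle inhibitor Cdkn1a at 7.79-fold. The cell proliferation list stood at 0.72 (0.53 to 0.94; 0.54 relative to all genes), and the replication genes Mcm2, Rrm2, Mcm3 and Mcm5 were 3.19-fold, 2.25-fold, 2.34-fold and 2.86-fold higher. In cluster 12 the list was lower, at −0.92 (−1.22 to −0.19), with 14 of 31 over 2-fold lower.

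The placental hormone list was mixed, with more genes far lower than far higher in the library labelled knockout. Of 42 prolactin-family and pregnancy hormone genes, 19 were over 2-fold lower and 8 over 2-fold higher (median −0.36, −2.38 to 0.43; −0.53 relative to all genes). Prl3b1, placental lactogen II, stood at 290 against 1114 CPM, 3.83-fold lower (3.76 to 3.91), Prl2b1 was 4.64-fold lower, and Prl8a9 and Prl7a2 were both 2.33-fold lower. The spongiotrophoblast marker Tpbpa stood at 610 against 2493 CPM, 4.09-fold lower (4.03 to 4.14), and Flt1, a decoy receptor for vascular growth factor, at 1699 against 4620 CPM, 2.72-fold lower. Prl3d1, placental lactogen I and a gene leading cluster 12, was 6.11-fold higher (5.21 to 7.21). Without the clusters mostly of 1 library, the log2 ratios of Prl3b1, Prl8a9 and Prl7a2 were 0.11, 0.25 and 0.84. Spongiotrophoblast-like and glycogen cell-like cells made up less of trophoblast in the library labelled knockout. The pooled ratios of Tpbpa and Flt1 can therefore not be read as differences within a subtype.

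The list of syncytiotrophoblast fusion and nutrient transport had a median of 0.48 (0.03 to 0.72; 0.31 relative to all genes) with 6 of 28 over 2-fold higher. The fusogen gene Synb was 2.06-fold higher (1.92 to 2.20), the lactate transporter Slc16a1 2.27-fold, the folate transporter Slc19a1 2.11-fold and the tight junction gene Cldn3 5.89-fold, while Gcm1, which drives syncytiotrophoblast formation, stood at 32.8 against 28.7 CPM. Of 25 angiogenesis genes, 12 were over 2-fold higher and 2 lower (median 0.99, 0.43 to 1.20; 0.81 relative to all genes), with Vegfa 2.08-fold higher and the endothelial genes Pecam1 and Angpt1 4.83-fold and 5.81-fold higher. Endothelium-like cells were also more frequent in the library labelled knockout (14.7% against 7.62%). In them the list stood at −0.061 (−0.24 to 0.22), and in decidual stroma-like, macrophage-like and erythroid-like cells at 0.45, 0.96 and 2.48. Nrp1, a semaphorin and growth factor receptor, was 2.25-fold higher, but with cluster 11 counted as trophoblast its log2 ratio was −0.029.

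Hypoxia and glycolysis genes had a median of 0.37 (−0.06 to 0.70; 0.19 relative to all genes), with Egln3, an oxygen sensor, 2.39-fold higher. Sterol synthesis genes stood at −0.02 (−0.36 to 0.34; −0.20 relative to all genes), none past 2-fold, with the receptor gene Ldlr 1.83-fold lower and its regulator Srebf2 1.54-fold higher. Nuclear-encoded oxidative phosphorylation genes stood at 0.27 (0.18 to 0.45; 0.09 relative to all genes), with 1 of 35 past 2-fold, Uqcrq of complex III at 2.07-fold. Nuclear-retained RNAs had a median of 0.67 (−0.11 to 1.35, and 0.50 relative to all genes), with Neat1 and Meg3 2.55-fold and 2.11-fold higher. Xist also stands on this list, at 7564 against 4.58 CPM, a difference bound up with fetal sex as described below.

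**Figure D3:**
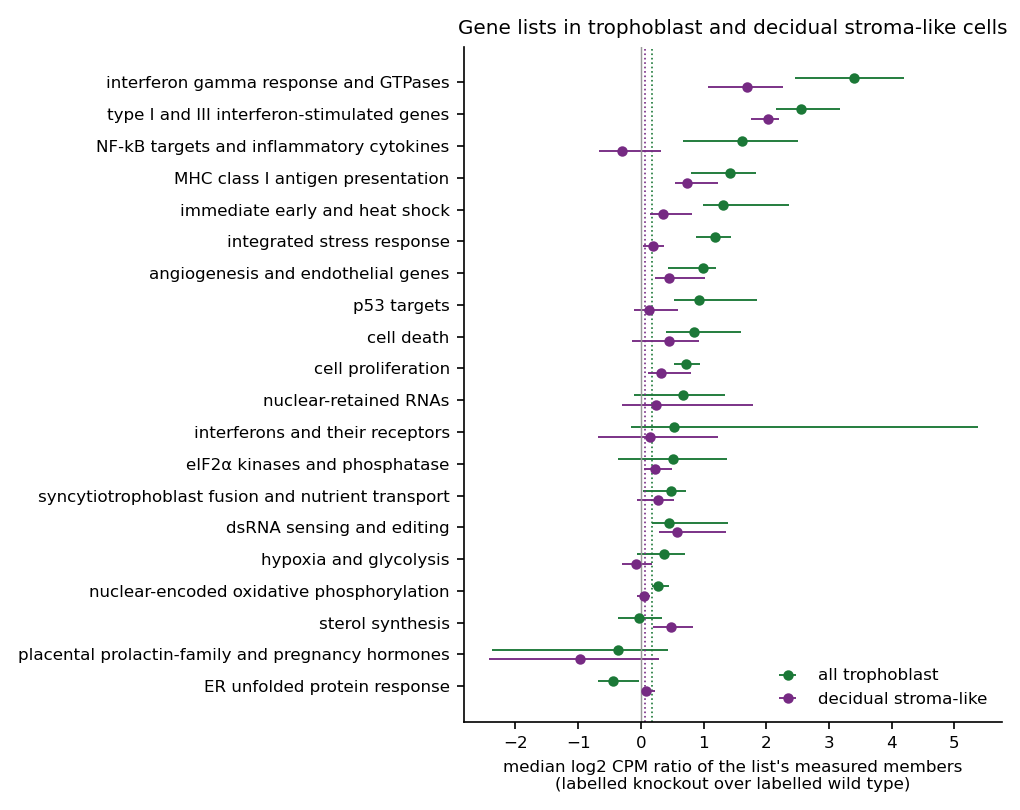
Median log2 ratio of CPM (labelled knockout over labelled wild type) of each gene list's measured members, in all trophoblast and in decidual stroma-like cells. Bars are 95% order-statistic intervals over the members and dotted lines are the medians of all genes; the interferon-stimulated genes stand at 2.55 and 2.02, the integrated stress response at 1.18 and 0.19.

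Apart from sex-linked genes, the 10 largest trophoblast ratios that the naming rule gives were mostly interferon-induced genes. They were Cxcl10, Iigp1 (an interferon-inducible GTPase; 41.0 against 0.388 CPM, a ratio of 106), Ifi44 (60.6), Ifit3 (47.9), Olfr56 (37.9), Oasl1 (34.6), Ifit2 (31.1), Gbp3 (22.8), Trib3 (19.4) and Prss12 (18.3). Oasl1 and Gbp3 were also among the genes that lead clusters 6 and 5. The 10 smallest were those of Chst9 (2.82 against 123 CPM, 43.6-fold lower), Psg26 (21.5-fold), Ceacam14 (21.3-fold), Prl3a1 (18.3-fold), Ctsm (18.2-fold), AU015791 (15.6-fold), Col15a1 (14.7-fold), Tpbpb (11.8-fold), Prl8a8 (11.8-fold) and Psg28 (11.4-fold). Chst9 leads the sinusoidal giant cell-like cluster 28, and Ceacam14, Ctsm, Prl8a8 and Psg28 lead the spongiotrophoblast-like cluster 22, both nearly all from the library labelled wild type.

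The interferon-stimulated genes were higher in the 6 trophoblast classes and clusters with at least 50 cells in both libraries; the sinusoidal giant cell-like class had 43 cells labelled knockout and was not compared. Their medians were 1.36 (1.08 to 1.92) in syncytiotrophoblast I-like, 1.30 (0.83 to 1.60) in syncytiotrophoblast II-like, 2.85 (2.48 to 3.16) in spongiotrophoblast-like and 2.73 (2.48 to 3.43) in glycogen cell-like cells, and 2.97 (2.73 to 3.44) and 1.69 (1.46 to 2.14) in clusters 5 and 12. In the unnamed clusters 8 and 11, which are outside the trophoblast sums, they were 1.80 and 1.82. The integrated stress response list had its highest median in syncytiotrophoblast I-like cells, at 2.13 (1.44 to 2.63). There 42 of 57 members were over 2-fold higher, ribosomal protein genes stood at 1.64 and immediate early genes at 0.98. That class was nearly all of a different cluster in each library. The ratios of that class therefore cannot be read as differences within a subtype. The other medians of the stress list were 0.72 in syncytiotrophoblast II-like, 0.80 in spongiotrophoblast-like, 1.07 in glycogen cell-like, and 1.18 and 1.31 in clusters 5 and 12. Ribosomal protein genes stood at 0.90, 1.30, 0.78, 0.90 and 0.61 in the same order, above the stress list in syncytiotrophoblast II-like and spongiotrophoblast-like cells and below it in the others. Immediate early genes stood above the stress list in spongiotrophoblast-like (1.44) and glycogen cell-like cells (1.23). They stood below it in syncytiotrophoblast II-like cells (0.70) and cluster 12 (1.11). Beginning with syncytiotrophoblast I-like cells, the 6 trophoblast classes and clusters had all-gene medians of 0.29, 0.13, 0.29, 0.16, 0.16 and −0.14. None of the differences between classes was tested.

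In syncytiotrophoblast I-like cells Trib3 stood at 83.8 against 0.225 CPM (765 and 3 UMIs), a ratio of 373 (127 to 1812). The other largest ratios were of Gpr132, a receptor on immune cells (139), and Lhfpl2 (56.0). The smallest were of Frem2, a basement membrane gene (40.9-fold lower), Itpka (26.8-fold) and Zfp385c (23-fold). All these ratios set mostly different clusters of the class against each other, as described above. In spongiotrophoblast-like cells the largest were Acod1, which makes the antimicrobial itaconate (59.2 CPM against 0 UMIs, at least 347-fold higher), Oasl1 (136) and Ifi44 (133), and the smallest Acacb (30.04-fold lower), Derl3 (17.2-fold) and Stab2 (16.7-fold). The ER unfolded protein response list was lower in that class, at −0.84 (−1.47 to −0.67), with 9 of 23 over 2-fold lower, and Dnajc3 and Herpud1 at 2.80-fold and 2.77-fold lower. It was not lower in glycogen cell-like cells, at 0.33 (0.28 to 0.50) with 1 of 23 over 2-fold higher, or in syncytiotrophoblast II-like cells, at 0.21 (0.091 to 0.50), an interval that holds the class's all-gene median of 0.13. In glycogen cell-like cells the largest ratios were of Ifit2 (134), Rsad2 (23) and Ddx60 (16.3), and the smallest of Clec9a, Clec1b and AU015791 (17.4-fold, 14.6-fold and 14.1-fold lower). In syncytiotrophoblast II-like cells Rsad2 was again the largest, at 14.6. In cluster 5 they were Rbfox1 (82.1), Ifit2 (at least 76.2) and Ifit1 (74.7).

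Outside trophoblast, interferon-stimulated genes were higher in each class measured. In decidual stroma-like cells they had a median of 2.02 (1.75 to 2.21), with 60 of 70 over 2-fold higher (2357 and 394 cells; all-gene median 0.07). Ddx60, a helicase of RNA sensing, stood at 602 against 87.8 CPM, Oasl2 was 4.84-fold higher, Trim30a 5.54-fold and the signal transducer Stat2 4.09-fold. Ifi44 (33.6, 15.4 to 91.8), Oas2 (17.3) and the calcium channel gene Cacnb2 (15.7) had the largest ratios there. Interferon gamma and GTPase genes stood at 1.70 (1.08 to 2.27), and MHC class I genes at 0.73 (0.55 to 1.23). The integrated stress response list stood at 0.19 (0.03 to 0.37), with 6 of 56 over 2-fold higher, and NF-kB targets at −0.31 (−0.66 to 0.32).

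In endothelium-like cells the interferon-stimulated genes had a median of 0.85 (0.71 to 0.97), with Rsad2 at 764 against 332 CPM, and in pericyte or mesenchyme-like cells 0.78 (0.58 to 1.01). They stood at 0.92 (0.83 to 1.17) in macrophage-like, 1.63 (1.16 to 2.21) in B cell-like and 2.15 (1.29 to 2.88) in erythroid-like cells, where 24 members were measured. Trophoblast RNA in the droplets as a source of these genes was tested for decidual stroma-like cells only, and not for these classes. The integrated stress response list stood at 0.96 (0.56 to 1.24) in macrophage-like cells, 0.53 in mesenchyme-like, 0.40 in endothelium-like, 0.54 in B cell-like and 0.32 in erythroid-like cells, and at 0.43 and 0.34 in clusters 8 and 11. Ribosomal protein genes stood at −0.92 in erythroid-like cells and between 0.21 and 0.58 in the other named non-trophoblast classes, and at 0.42 and 0.95 in clusters 8 and 11. In macrophage-like cells the elastase gene Mmp12 (190 and 2 UMIs; interval of the ratio 25.3 to 771) and the interferon-induced Slfn4 (25.1) had the largest ratios, and in endothelium-like cells Prap1, which leads cluster 3 (169 CPM against 0 UMIs, at least 228-fold). The spongiotrophoblast gene Tpbpb was 16.5-fold lower in decidual stroma-like, 13.4-fold in endothelium-like and 37.3-fold in macrophage-like cells. Tpbpb was also lower in trophoblast, and trophoblast RNA in the droplets was not tested as the source of its UMIs here. Decidual stroma-like cells labelled knockout held trophoblast markers at a median of 9.23% of the trophoblast level. Those labelled wild type held Y-linked genes at 25.2 CPM. The Tpbpb ratios therefore cannot be read as differences within these classes.

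**Figure D4:**
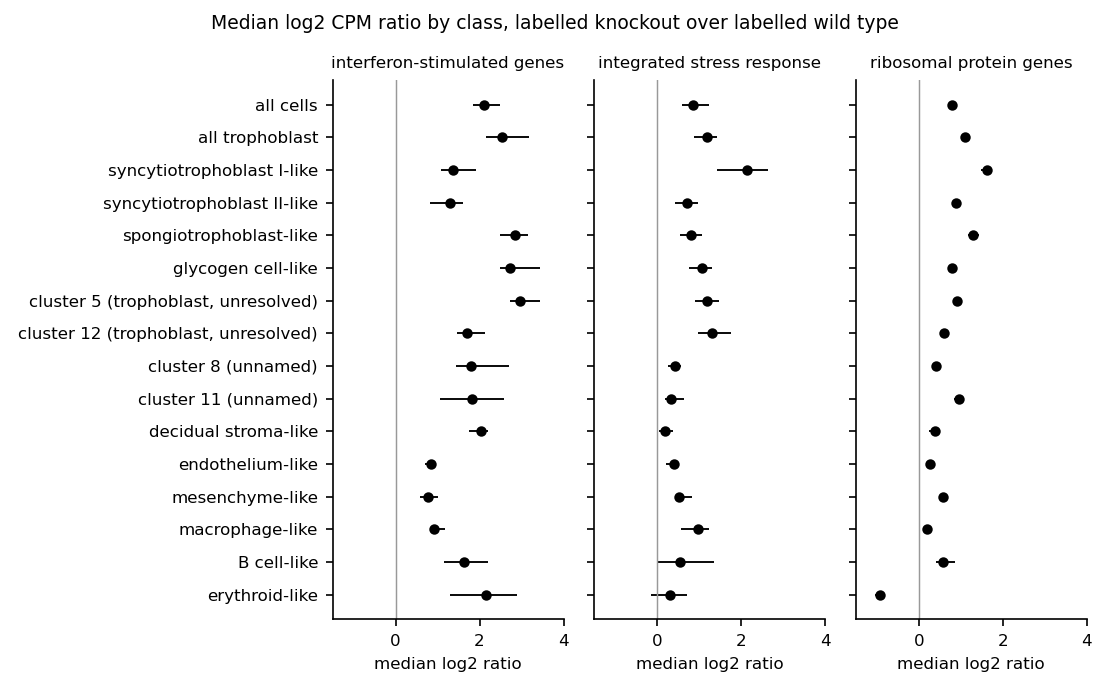
Median log2 ratio of CPM (labelled knockout over labelled wild type) by cell class for interferon-stimulated, integrated stress response and ribosomal protein genes; bars are 95% order-statistic intervals over the genes of each list. Interferon-stimulated genes range from 0.78 in mesenchyme-like cells to 2.97 in cluster 5, and the stress list from 0.19 in decidual stroma-like to 2.13 in syncytiotrophoblast I-like cells. The syncytiotrophoblast I-like cells were nearly all of a different cluster in each library.

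Summed over all cells, which mixes composition with expression, 65 of 74 interferon-stimulated genes were over 2-fold higher in the library labelled knockout, with a median of 2.11 (1.85 to 2.49; 2.01 relative to all genes, whose median was 0.11). The integrated stress response list stood at 0.86 (0.59 to 1.24), with 27 of 58 over 2-fold higher. Chac1 was 19.4-fold higher (7.16 to 73.5), with 57 and 4 UMIs. Few of its UMIs were in trophoblast, so this ratio rests mainly on other cells, whose shares differed between the libraries. The largest ratios were of Zfp804a (24.7 against 0.742 CPM, 33.2-fold), A2m (24.7-fold), Ifit3 (21-fold), Sez6l (20.4-fold), Oasl1 (18.5-fold), Ifit2 (18.4-fold), Oas2 (16.8-fold), Adamts5 (16.7-fold), Rimklb (16.7-fold) and Mlph (15.5-fold), of which A2m, Sez6l, Adamts5 and Rimklb lead decidual clusters 2 and 13. The smallest were of Chst9 (54.7-fold lower), Psg26 (30.2-fold), Ceacam14 (30.03-fold), Ctsm (24.7-fold), Tpbpb (16.2-fold), Prl8a8 (16.1-fold), Psg28 (15.5-fold), Ceacam12 (15.2-fold), Cts6 (14.4-fold) and Ceacam3 (13.7-fold). Of these, Chst9 and Cts6 lead cluster 28, and Ceacam14, Ctsm, Prl8a8, Psg28 and Ceacam12 lead cluster 22.

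Fetal sex was wholly confounded with the genotype label. In trophoblast, Xist, the RNA of the inactive X chromosome, stood at 7564 against 4.58 CPM and the 4 Y-linked genes together at 0.218 against 469 CPM, and the list of Xist and Y-linked genes had a median of −9.17 with 1 member higher and 4 lower. In decidual stroma-like cells Xist stood at 2643 against 2751 CPM and the Y-linked genes at 0.260 against 25.2 CPM.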

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

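Of the tests described here, those on free and macrophage RNA as sources of the UMIs of 3 interferon genes were chosen before their outcome was known, and all others only after the result was seen. Cell proliferation genes were lower in macrophage-like cells of the library labelled knockout, with a median log2 ratio of −1.19 (−1.75 to −0.62) and 12 of 21 over 2-fold lower. They were higher in syncytiotrophoblast I-like cells (1.16), erythroid-like cells (1.30) and cluster 5 (1.38). Smaller medians went both ways. Cluster 12 was lower, at −0.92 (−1.22 to −0.19), as were mesenchyme-like cells, at −0.39 (−0.56 to −0.30). Spongiotrophoblast-like (0.87), glycogen cell-like (0.83) and endothelium-like cells (0.39) were higher. Immediate early and heat shock genes were lower in erythroid-like cells, at −1.31 (−2.01 to −0.60), and higher in cluster 12 (1.11), glycogen cell-like (1.23), macrophage-like (1.34) and spongiotrophoblast-like cells (1.44). The differences between classes were not tested, since each class has 1 sample per genotype.

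The interferon-stimulated genes were higher in both trophoblast and decidual stroma-like cells, and trophoblast RNA in the droplets of decidual cells was tested as a source. In the library labelled knockout these genes stood in decidual cells at a median log2 of −0.21 (−0.44 to 0.38) relative to trophoblast, while 80 trophoblast markers stood at −3.44 (−3.52 to −3.12). The difference of 3.23 speaks against free trophoblast RNA as the main source. In pooled trophoblast the genes also lay 1.44 above the ribosomal protein genes, which speaks against a larger share of cytoplasmic RNA as the whole cause there. The order was reversed in syncytiotrophoblast I-like cells, at 1.36 (1.08 to 1.92) against 1.64 (1.49 to 1.72) for the ribosomal protein genes. In each other trophoblast class or cluster compared, the interferon-stimulated genes had the higher median. For syncytiotrophoblast I-like cells this explanation stays open. Xist in decidual cells differed little between libraries (ratio 0.961, 0.937 to 0.985). Decidual cells are maternal and so female in either library, so this outcome was fixed in advance and does not bear on fetal sex. In trophoblast the ratio was 1650, and an effect of fetal sex, litter or batch cannot be told from one of genotype.

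The integrated stress response list in trophoblast lay only 0.075 above the ribosomal protein genes, which alone would leave room for a larger share of spliced, cytoplasmic RNA in the library labelled knockout. The oxidative phosphorylation genes, the other such yardstick, stood at 0.27 (0.18 to 0.45), well below the list's 1.18 (0.88 to 1.44), so the yardsticks differed and this explanation stays open. The immediate early and heat shock genes were higher too, at 1.30 (0.99 to 2.37) against an all-gene median of 0.17, a direction that more stress during tissue handling would also give. These data do not separate either from a response within the tissue.

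The UMIs of Ifnb1, Ifnl2 and Ifnl3 were 233 in 60 cells, or 3.88 per cell holding any, with up to 30 in 1 cell. Random placement by depth gave a median of 1.02 over 1000 draws, of which the central 95% ended at 1.04, which speaks against RNA free in the droplets. Macrophage marker RNA in the 57 trophoblast cells among them stood at 4.36% (upper bound 5.21%) of the level in macrophage-like cells, where droplets that also held a macrophage would need 33.4%. Other cells of the same trophoblast classes held 326 CPM of these markers, against 256 CPM in the cells with interferon UMIs and 5862 CPM in macrophage-like cells.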

How the results depend on the processing

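Of the alternatives, 6 were chosen only after the results were seen: the 3 on trophoblast membership and weighting, the totals without the 20 most abundant genes, and the shares without decidual cells or of trophoblast only. No paired analysis was possible because no cell can be tied to any of the 5 samples of its genotype, and for the same reason no sample could be left out.

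The interferon-stimulated genes kept their direction under every alternative run: in all cells their median log2 ratio lay between 1.93 and 2.13, in decidual stroma-like cells between 1.79 and 2.05, and 58 to 66 trophoblast members were over 2-fold higher (67 over 1.5-fold). In trophoblast their median lay within its interval except without clusters over 90% of 1 library, where it was 3.19; there the integrated stress response list stood at 1.44. The decidual share (log2 ratio 2.56) lay between 2.53 and 2.56.

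The trophoblast log2 ratio of Adar (1.38) was 1.25 under median-ratio scaling, 1.18 under TMM, 1.52 for mean per-cell values, 1.51 for thinned cells, 1.25 with doublets kept, 1.25 at resolution 2, 1.24 with each matrix clustered alone, 1.32 with classes weighted alike and 2.07 without the clusters of 1 library. The log2 ratio of the sinusoidal giant cell-like share (−4.76) was −0.95 at resolution 0.5, −5.28 at resolution 2, −5.36 at 10% mitochondrial UMIs, −5.40 with the response lists among the variable genes and −4.17 as a share of trophoblast. With each matrix clustered alone no cell labelled knockout took the name, which gives −8.84 at the floor of 3 cells. The share of trophoblast cells with an Isg15 UMI (9.80% and 1.22%) was 16.6% and 2.16% thinned to 2000 UMIs and 37.0% and 9.12% unthinned; the share labelled knockout was 7.56% with doublets kept, 7.67% at resolution 2 and 7.74% with each matrix clustered alone.

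Without the clusters of 1 library, the trophoblast ER unfolded protein response list turned to 0.090, and Prl3b1, Prl8a9 and Prl7a2 turned to 0.11, 0.25 and 0.84. Nrp1 turned to −0.029 with cluster 11 counted as trophoblast. The cause was not tested in any of these cases.

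Turning was counted only where the main interval excluded no difference and, for genes and shares, the main ratio was past 2-fold. The genes and lists counted were those reported here, and many of the genes were named for the size of their ratio in these same data. Such genes seldom turn, so the counts do not describe genes in general. Of 2631 values for single genes, 706 left their counting interval, and of the 2506 so counted 4 turned. Of 1352 list medians, 60 left their interval, and of 1001 counted 1 turned. Of 159 shares, 34 left theirs, and of 66 counted none turned. Smaller differences could change sign uncounted. The syncytiotrophoblast I-like share was 11.1% against 11.8% of all cells but 24.9% against 17.6% of trophoblast.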

Other observations

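Macrophage-like cells of the library labelled knockout (269 cells, against 193) had higher hypoxia and glycolysis genes, with a median log2 ratio of 1.23 (1.04 to 1.43) and 17 of 22 over 2-fold higher. The glycolytic genes Pkm, Pfkp, Gpi1 and Gapdh were 2.37-fold, 2.26-fold, 2.22-fold and 2.69-fold higher, and the proliferation genes Top2a (53.3 against 158 CPM) and Mki67 (15.6 against 108 CPM) were lower. In the same cells Xist stood at 2672 against 313 CPM and the Y-linked genes at 1.30 against 545 CPM, and in the library labelled wild type 56.0% of them held a Y-linked UMI while 26.4% held Xist and no Y-linked UMI. That class was therefore of mixed sex there, so a different mix of fetal and maternal macrophages in the 2 libraries was not excluded as a source of these ratios. Immediate early and heat shock genes stood at 1.34 (0.92 to 1.89) in the same cells, with 15 of 23 over 2-fold higher. More stress during tissue handling was therefore not excluded either.

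At the main clustering, marker genes of sinusoidal giant cells differed less in trophoblast sums than the share of such cells among trophoblast did. That share was 18.1-fold lower (13.3 to 25.1) in the library labelled knockout. The 9 marker genes had a median log2 ratio of −1.07 (−2.17 to −0.05), 5 of them over 2-fold lower and 1 higher. At a resolution of 0.5 the log2 ratio was −0.95, but for the share of all retained cells. The share among trophoblast was not taken at that resolution, so the contrast cannot be said to hold there. Lepr stood at 417 against 1874 CPM, Nos1ap at 80.9 against 336 CPM and Ctsq at 1061 against 2230 CPM, while Prl2a1 stood at 165 against 80.2 CPM. Lepr and Ctsq lead cluster 28, nearly all from the library labelled wild type. These tests were chosen after the share had been seen.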
